A study of Homo sapiens with 90 samples.

How the data were processed

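Gene expression was measured by RNA sequencing in 90 subcutaneous tumours grown in mice from 10 patient-derived xenograft models of pancreatic cancer. The models are called A to J here. Each model was given vehicle, palbociclib at 100 mg/kg, or palbociclib with TAK228 (also MLN0128) at 0.5 mg/kg, by daily gavage for 5 days, and 3 mice per model and treatment were sequenced, per the labels' protocols. Groups were taken from the labels, and each library was taken as a separate mouse. This is doubtful for 2 combination libraries of model I, whose titles share a code apart from a suffix and which may come from 1 mouse. Their reads differed beyond counting noise (chi-square per degree of freedom 19.2, against 7.52 for the closest pair of that model), so they are not 1 library counted again, and another setting averages them.

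The submitters' processing notes list TopHat2, HTSeq and edgeR without versions, and the human build hg19 and the mouse build mm10. How reads from the mouse host were separated from tumour reads is not given in the sources used here. The authors deposited 1 table per model, with 56884 gene symbols and 9 libraries, as log2 values. Undoing the logarithm gave, in each library, whole multiples of a fixed step, with a tolerance of 0.05, for 100% of the values under 1000 steps, so that reads per gene were recovered. Reads in genes ran from 8.99 to 30.0 M per library, with a median of 17.5 M. The deposited values are log2 CPM with a small prior count, scaled within each table: columns summed to between 540898 and 1211826 after the logarithm was undone. Because the 10 tables were scaled separately, each fold change was made inside its own table, and no level was compared between models.

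CPM values were obtained as the linear value less that of a gene with no reads, with 1 constant per table so that the mean column total became the same in all tables. This keeps the authors' scaling between the libraries of a model. Fold changes are differences of group means of log2(value + 1), which understates changes of genes with few reads. A gene was tested across models when its table mean was at least 1 CPM in at least 5 tables, which left 14080 genes. Y-linked genes, XIST, HLA genes and genes of variable germline copy number were left out (1086 symbols). The annotation given here (GENCODE on a later human build) matched 65.6% of symbols and was used for gene types and Y-linked names, so no coordinates are given.

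The design was fixed for CPM values before the data were examined, and the log2 tables were brought to that scale. For each of 3 contrasts, the 10 within-model log2 fold changes of a gene were tested with limma 3.58.1 in R 4.3.3 (intercept only, empirical Bayes with trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Errors of genes are standard errors of this fit over n = 10 models unless called SD. The 34 gene lists were fixed at the same time. A list was tested where at least 5 members were expressed, which left 28 lists. Its mean log2 fold change per model was tested with an exact two-sided sign-flip permutation test over the 10 models, whose smallest possible p is 0.00195, with Benjamini-Hochberg adjustment over 84 tests. Within each model, limma with trend was fitted to the 9 libraries, with a table mean of at least 1 CPM. Differences between models in a list's response were tested by an interaction F with residuals permuted 100000 times in 60 libraries per contrast. No test of a single value was made inside a model, since an exact permutation test of 3 against 3 mice has 10 splits and a smallest p of 0.1.

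Genes are named by a rule fixed beforehand: the 10 with the largest rise and the 10 with the largest fall among genes past the threshold and changed alike in at least 9 of 10 models, 14 fixed genes of the cell cycle and growth signalling, and the 3 members with the largest change in each list that passed. The values of 3 genes that this rule names are not given. Members outside this rule that are named with their values were chosen after these were seen.

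Other settings were other pseudocounts, no filter, libraries rescaled to the same total or with TMM factors (trimmed mean of M values, computed from the recovered reads), fold changes centred on the median gene of each model, medians of mice, 1 fit over the 90 libraries, and the removal of models, mice or doubtful libraries. voom on the recovered reads, the deposited log2 values taken as they stand, and 2 removals of libraries were added after the data were seen. The steps were tested on simulated reads drawn from the real means, spreads and depths, with 200 genes changed by known folds. For palbociclib against vehicle, with 14047 genes in the step, 100% of genes lowered 4-fold, 87.5% of those lowered 2-fold, 83.3% of those raised 2-fold and 100% of those raised 4-fold were called across models, with 6 calls among 13852 unchanged genes. Inside single models, with 13368 to 15218 genes, a median of 73.4% of 4-fold and 33.3% of 2-fold changes were called. Genes were drawn independently, unchanged genes did not vary in response between models, and no scaling shift between libraries was simulated. The calls among unchanged genes therefore do not cover errors from these sources. Changed genes were drawn only from genes above a higher expression floor than that of the tests. Their changes varied less between models than those of some named genes, such as MKI67 (SD 1.32 with palbociclib). The shares called therefore do not cover genes with fewer reads or with more variable responses. Figures were drawn with matplotlib 3.10.9.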

Results

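Tumours of 10 pancreatic cancer xenograft models were compared after 5 days of vehicle, palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, or palbociclib with TAK228, an inhibitor of the growth kinase mTOR. Patient-derived xenografts are human tumours propagated in mice. Each model had 3 mice per treatment, so each treatment had 30 libraries. Mean depth was 19.3 ± 4.01 M reads in genes (SD, n = 30) with vehicle, 16.5 ± 3.0 M with palbociclib and 17.7 ± 4.31 M with the combination. Values are log2 fold changes of the authors' normalized CPM (read counts scaled to library size) with 1 added. They are means over the 10 models.

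The first comparison asked how palbociclib alone changed the tumours. Transcripts of cell division fell in all 10 models. MKI67, the proliferation marker Ki-67, fell by 3.12 ± 0.33 (SE, n = 10 models), which is 8.70-fold lower, and TOP2A, the topoisomerase that untangles DNA before mitosis, fell by 3.22 ± 0.34. RRM2, a subunit of the ribonucleotide reductase that makes DNA precursors, fell by 2.89 ± 0.32. Their limma adjusted p was 3.54e-05, 3.01e-05 and 4.19e-05. The other genes with the largest falls were KIF20A, CENPF, NUSAP1, DLGAP5, BIRC5, MYBL2 and HMGB2, with log2 changes between -3.00 and -2.78, each lower in 10 of 10 models.

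All 48 measured members of the mitosis list and all 47 of the DNA replication list fell, and the same counts held when adjusted over the list alone. The mitosis list changed by -2.44 ± 0.94 (SD, n = 10 models) and the DNA replication list by -1.35 ± 0.62, both lower in 10 of 10 models (exact sign-flip p = 0.00195, the smallest the test can give, adjusted p = 0.0137). Of the homologous recombination list, which repairs double-strand breaks, 18 of 19 members fell (19 adjusted over the list alone), among them EXO1 (-1.98 ± 0.22), RAD51AP1 (-1.80 ± 0.22) and FANCI (-1.76 ± 0.22). This list changed by -1.28 ± 0.61 (SD), with an adjusted p of 0.0137.

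Genes of the G1 to S transition went both ways. Of 20 list members, 11 fell and 1 rose (12 and 2 adjusted over the list alone). The list changed by -0.48 ± 0.16 (SD, 10 of 10 models, exact sign-flip adjusted p = 0.0137). CCND2, a D-type cyclin that activates CDK4 and CDK6, rose by 1.17 ± 0.27, higher in 9 of 10 models, with a limma adjusted p of 0.00841. CCND1, the most studied D-type cyclin, was 0.45 ± 0.16 higher in 9 of 10 models but missed the threshold (adjusted p = 0.0664). The E-type cyclin CCNE2 fell by 1.31 ± 0.18 and CCNE1 was at -0.43 ± 0.17 (adjusted p = 0.0803). Among the largest falls of the list were CDKN2C (-1.76 ± 0.19), an inhibitor of CDK4 and CDK6, and RBL1 (-1.47 ± 0.21), a relative of the retinoblastoma protein. E2F1 was at -1.08 ± 0.22, the inhibitor CDKN1B at -0.80 ± 0.13, CDK4 at -0.66 ± 0.15, CDK2 at -0.61 ± 0.11 and RB1 at -0.47 ± 0.10, with limma adjusted p of at most 0.00695. CDK6 (-0.14), CDKN1A (-0.03), MYC (0.00) and IRS2 (-0.37) had adjusted p-values from 0.102 to 0.986.

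Fewer genes were higher. Besides CCND2 they were led by FBXO2 (0.94), QPRT (0.92), MYOM3 (0.91), APOE (0.89), CST6 (0.88), DKK3 (0.88), LUM (0.83), L1CAM (0.81) and FAM155A (0.78), each higher in at least 9 of 10 models with limma adjusted p between 0.00625 and 0.0172. LUM encodes lumican, a collagen-binding protein of connective tissue, and belongs to the fibroblast list. How mouse host reads were separated is not given, so values of LUM and of the fibroblast list in every contrast can include reads from mouse stroma. The other 6 measured members of that list, COL1A1, COL5A2, SPARC, PDGFRA, FBN1 and TAGLN, did not pass the test, with changes from -0.13 to 0.51. Without 3 libraries that stand apart from their tables (palbociclib 1 and 2 of model E and palbociclib 3 of model B), LUM (0.48, limma adjusted p = 0.336) and MYOM3 (0.61, adjusted p = 0.0628) no longer passed, while CCND1 did (0.48, adjusted p = 0.0427).

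In total 2769 of 14080 genes changed with palbociclib, 54 higher and 2715 lower, and of these 1 rose and 259 fell by 2-fold or more. Within models E and F, in which title tags differ between treatments, the balance was the opposite, with 1091 higher and 804 lower in E and 1472 higher and 1140 lower in F. The split across models depends on the scaling: the median of all genes was -0.18, and with TMM factors 841 genes changed, 236 higher and 605 lower. With each model centred on its median gene, 974 changed, 303 higher and 671 lower. Relative to the median gene the mitosis list changed by -2.25 ± 1.01 (SD), the DNA replication list by -1.17 ± 0.70 and the G1 list by -0.30 ± 0.23 (exact sign-flip adjusted p = 0.0109, 0.0109 and 0.0189). CCND1 was 0.63 above the median gene (limma adjusted p = 0.0222), while CDK4 (-0.48) and RB1 (-0.28) no longer passed (adjusted p = 0.0679 and 0.114), nor did UTP20 (-0.51) and LYAR (-0.49), 2 genes of ribosome biogenesis (adjusted p = 0.0725 and 0.0565). The ribosome biogenesis list, led by NPM1 (-0.76), UTP20 (-0.69) and LYAR (-0.68), changed by -0.38 ± 0.26 in the authors' scaling (18 of 29 members lower, 22 adjusted over the list alone, exact sign-flip adjusted p = 0.0290) and by -0.20 ± 0.28 relative to the median gene (adjusted p = 0.125). The lysosome list was at 0.08 ± 0.27 in the authors' scaling (adjusted p = 0.512) and at 0.27 ± 0.16 relative to the median gene, higher in 10 of 10 models (adjusted p = 0.0109). The fibroblast list stood at 0.21 ± 0.28 (adjusted p = 0.119) and, relative to the median gene, at 0.39 ± 0.33 (adjusted p = 0.0149). The antigen processing list changed sign, from -0.07 ± 0.24 (adjusted p = 0.548) to 0.12 ± 0.13 relative to the median gene (adjusted p = 0.041).

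The lists of glycolysis and hypoxia (-0.46 ± 0.62), oxidative phosphorylation (-0.29 ± 0.32), fatty acid synthesis (-0.23 ± 0.27), cholesterol synthesis (-0.19 ± 0.40) and p53 targets (-0.17 ± 0.22) did not pass with palbociclib, with exact sign-flip adjusted p from 0.082 to 0.299. Interferon-stimulated genes, which respond to viral signals, stood at 0.06 ± 0.60, with 4 of 10 models higher (adjusted p = 0.844). Secreted factors of senescent cells stood at 0.05 ± 0.50 (adjusted p = 0.848). The markers of the classical and basal-like subtypes of pancreatic cancer stood at -0.11 ± 0.76 and 0.00 ± 0.67 (adjusted p = 0.785 and 0.986). The remaining 11 lists, from ATF4 targets to immune cell markers, lay between -0.33 and 0.03 and had adjusted p from 0.106 to 0.915.

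By model, the mitosis list changed by -3.77 in model E, -3.50 in D, -3.19 in A and -3.11 in I, against -1.09 in G, -1.38 in H, -1.65 in C and -1.79 in F. The interaction permutation test did not show a difference between models for the mitosis list (F = 1.93, adjusted p = 0.18) or the DNA replication list (F = 1.82, adjusted p = 0.191) with palbociclib. Within single models limma called a median of 803 genes, from 0 in models B and H and 1 in G to 2612 in F and 3031 in I. At an unadjusted p under 0.05, limma counted 677 genes in model B and 957 in H, where chance alone gives about 686 and 678. Model B still had a mitosis list change of -2.37. Its genes had a median SD of 0.486 between mice of a group, the largest of all models. Its palbociclib library 3 stood apart, with a median correlation of 0.815 with the other libraries.

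Some libraries differ in the tags of their titles or in a suffix of their column names, and the drug effect was looked at within these where both treatments were present. In model F, the 1 palbociclib library with the tag of the vehicle libraries had a mitosis list change of -1.20, against -2.08 for the 2 with another tag. In model E, the palbociclib library with the tag of the combination libraries was at -2.58 and the 2 others at -4.37, and none shared the tag of the vehicle libraries. In model C, the palbociclib library without the suffix LT, whose meaning is not given in the labels, was at -2.98 and the 2 with it at -0.99. No error can be given for a single library.

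**Figure D1:**
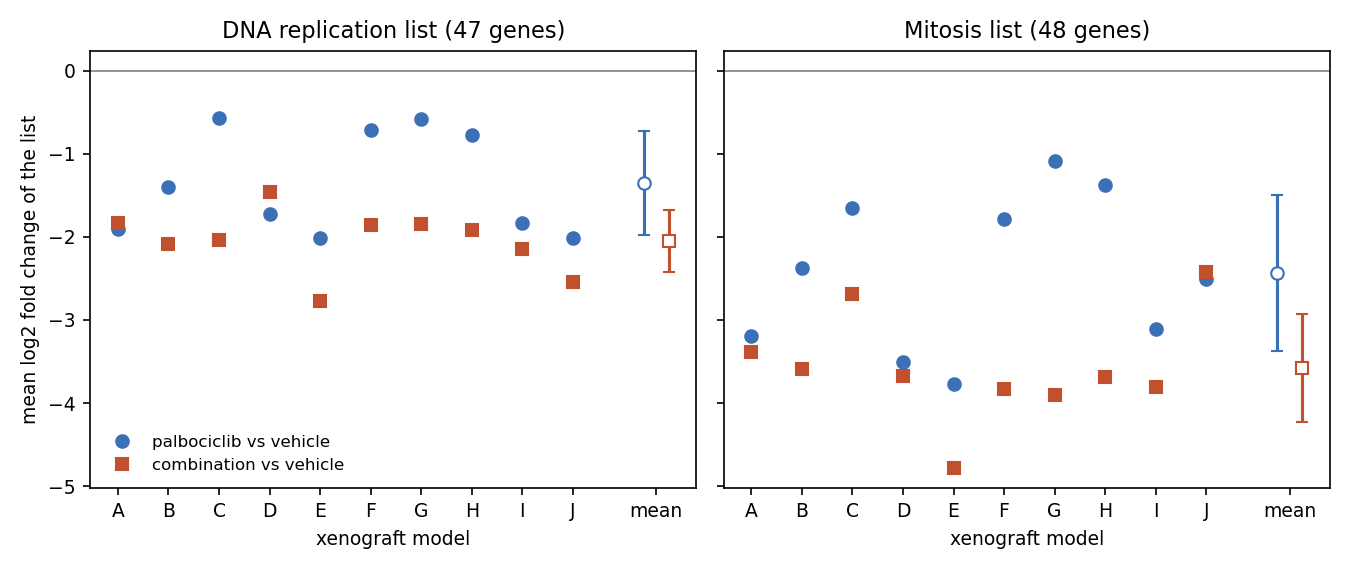
Mean log2 fold change (vertical axes) of the DNA replication list and the mitosis list in each xenograft model (horizontal axes) with palbociclib (circles) or the combination (squares) against vehicle, with the mean and SD of the 10 models in open symbols. Every model lies below 0 in both lists, and the mitosis list ranges from -3.77 to -1.09 with palbociclib and from -4.78 to -2.42 with the combination.

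The second comparison asked what palbociclib and TAK228 changed together against vehicle. Division genes were lower still against vehicle: MKI67 was at -5.26 ± 0.35 (38.3-fold lower), RRM2 at -4.93 ± 0.26, TOP2A at -4.85 ± 0.31 and MYBL2, a transcription factor of cell cycle genes, at -4.69 ± 0.21 (SE, n = 10 models). CENPF, NUSAP1, BIRC5, KIF20A, DLGAP5 and CCNA2 followed, with log2 changes from -4.46 to -4.09 and limma adjusted p of at most 3.03e-08. All 48 mitosis genes and all 47 DNA replication genes fell, also when adjusted over the list alone. Their lists changed by -3.58 ± 0.65 and -2.05 ± 0.37 (SD, 10 of 10 models, exact sign-flip adjusted p = 0.0137). The homologous recombination list changed by -1.88 ± 0.36 (adjusted p = 0.0137), with 18 of 19 members lower (19 adjusted over the list alone), led by EXO1 (-3.14), BRIP1 (-2.77) and RAD51AP1 (-2.75).

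The G1 list changed by -0.71 ± 0.22 (SD), with 10 of 20 members lower and CCND1 the only one higher, and the same counts adjusted over the list alone (exact sign-flip adjusted p = 0.0137). CCND1 rose by 0.53 ± 0.14, higher in 8 of 10 models (limma adjusted p = 0.0186), and CCND2 was at 0.11 ± 0.19 (adjusted p = 0.72). CDKN2C was at -2.51 ± 0.20, E2F1 at -2.25 ± 0.22, CDC25A at -2.08 ± 0.16, RBL1 at -2.07 ± 0.17, CCNE2 at -1.82 ± 0.16 and CDK2 at -0.89 ± 0.13. CCNE1 (-0.75), RB1 (-0.75), CDK4 (-0.74) and CDKN1B (-0.55) also fell, with adjusted p between 0.00209 and 0.0184. CDK6 (-0.13), CDKN1A (0.21), MYC (0.19) and IRS2 (0.38) did not pass, although relative to the median gene MYC was 0.36 higher and passed (adjusted p = 0.00824).

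Genes of lipid synthesis fell with the combination. Of the fatty acid synthesis list, 8 of 14 members fell (10 adjusted over the list alone), among them the desaturases FADS1 (-1.45 ± 0.17) and SCD (-1.17 ± 0.23) and the malic enzyme ME1 (-1.10 ± 0.19). Of the cholesterol synthesis list, 16 of 25 fell (17 adjusted over the list alone), including ACAT2 (-1.40 ± 0.20), which makes a precursor of sterols, and INSIG1 (-1.24 ± 0.19), a sterol sensor. The lists changed by -0.65 ± 0.37 and -0.63 ± 0.48 (SD), both lower in 10 of 10 models, with an exact sign-flip adjusted p of 0.0137. Relative to the median gene they were at -0.48 ± 0.31 and -0.46 ± 0.41 (adjusted p = 0.0109 and 0.0189). With palbociclib alone 2 of 14 and 4 of 25 members were already lower. Among these were FADS1 (-0.86) and ACAT2 (-0.67), lower in 10 of 10 models (limma adjusted p = 0.000521 and 0.000527). SCD (-0.24), ME1 (-0.40) and INSIG1 (-0.43) did not pass there. Between the combination and palbociclib no member of either list passed over all genes.

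Genes of oxidative phosphorylation, led by COX7B (-0.68), ATP5G3 (-0.61) and CYC1 (-0.60), changed by -0.39 ± 0.32 (SD) as a list, with 14 of 30 members lower (20 adjusted over the list alone, exact sign-flip adjusted p = 0.0137). Relative to the median gene it was at -0.22 ± 0.18 (adjusted p = 0.0149), with 9 members lower. With palbociclib alone 10 of 30 members were already lower (14 adjusted over the list alone), although the list did not pass (-0.29 ± 0.32). Between the combination and palbociclib the list was at -0.10 ± 0.28 (exact sign-flip adjusted p = 0.448), and no member passed. The p53 target list changed by -0.26 ± 0.26 (adjusted p = 0.0290), with 9 of 25 members lower and, adjusted over the list alone, 9 lower and 1 higher, led by CCNG1 (-0.89), GDF15 (-0.87) and DDB2 (-0.74). Relative to the median gene this list was at -0.09 ± 0.11 (adjusted p = 0.0483), with 5 members lower and 2 higher, and GDF15 no longer passed. The ribosome biogenesis list (UTP20 -0.68, LYAR -0.64, NPM1 -0.58) changed by -0.34 ± 0.30 (12 of 29 lower, 13 adjusted over the list alone, adjusted p = 0.0469) and by -0.17 ± 0.25 relative to the median gene (adjusted p = 0.130), where UTP20 and LYAR no longer passed.

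The largest rises with the combination were IGFL1 (1.62 ± 0.37), AKAP12, a scaffold of protein kinase A (1.59 ± 0.27), the matrix protease MMP9 (1.44 ± 0.32), the proteoglycan VCAN (1.34 ± 0.29) and ANXA6 (1.33 ± 0.30). C6orf15, TAGLN, SEMA7A, MELTF and COL22A1 rose by 1.26 to 1.30. Since the separation of mouse host reads is not given, genes of stroma such as VCAN and TAGLN can include mouse reads. The same holds for the mesenchymal list. The mesenchymal list changed by 0.33 ± 0.29 (SD, 9 of 10 models, exact sign-flip adjusted p = 0.0219), with 3 of 15 members higher, also adjusted over the list alone: the adhesion molecule L1CAM (0.98), fibronectin FN1 (0.63) and the protease MMP14 (0.49). It missed the threshold without models E and F, where fewer models are tested (0.21, adjusted p = 0.0571). The rises of FN1 and L1CAM were not particular to the combination. With palbociclib alone FN1 was at 0.80 ± 0.19 and L1CAM at 0.81 ± 0.21 (limma adjusted p = 0.00992 and 0.0149). MMP14 did not pass with palbociclib alone (0.29 ± 0.14, limma adjusted p = 0.154), nor did the list (0.025 ± 0.45, SD, exact sign-flip adjusted p = 0.915). Between the combination and palbociclib FN1 was at -0.17, L1CAM at 0.18 and MMP14 at 0.20 (adjusted p from 0.357 to 0.764), and the list at 0.31 ± 0.58 (exact sign-flip adjusted p = 0.179). Relative to the median gene, 4 more lists were higher: transcripts induced by ERK signalling (0.27 ± 0.22, 10 of 10 models), senescence-associated secreted factors (0.49 ± 0.40), lysosome genes (0.20 ± 0.16) and FOXO targets with receptor kinases (0.19 ± 0.20), with exact sign-flip adjusted p of 0.0109, 0.0149, 0.0339 and 0.0383. In the authors' scaling none of these passed, with adjusted p of 0.295, 0.0722, 0.844 and 0.892. The fibroblast list stood at -0.09 ± 0.33 (adjusted p = 0.535), with TAGLN, a smooth muscle and fibroblast marker, higher and COL5A2 lower, also adjusted over the list alone. Markers of the classical subtype stood at -0.52 ± 0.82 (adjusted p = 0.173), glycolysis genes at -0.29 ± 0.68 (adjusted p = 0.338), interferon-stimulated genes at -0.09 ± 0.64 (adjusted p = 0.8) and ribosomal proteins at 0.02 ± 0.64 (adjusted p = 0.92).

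In total 2517 genes changed with the combination, 237 higher and 2280 lower, with the median of all genes at -0.15. Centred on the median gene 1990 changed, 859 higher and 1131 lower, and with TMM factors 1850 changed, 738 higher and 1112 lower. Within single models limma called a median of 955.5 genes, from 46 in model B to 6550 in model C. This median was 2118 without vehicle 3 of model J, 502 without combination 2 and 542.5 without combination 1 of that model, and 399 without models E and F. In model C the mitosis list changed by -3.07 in the combination library without the suffix LT and by -2.50 in the 2 with it.

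**Figure D2:**
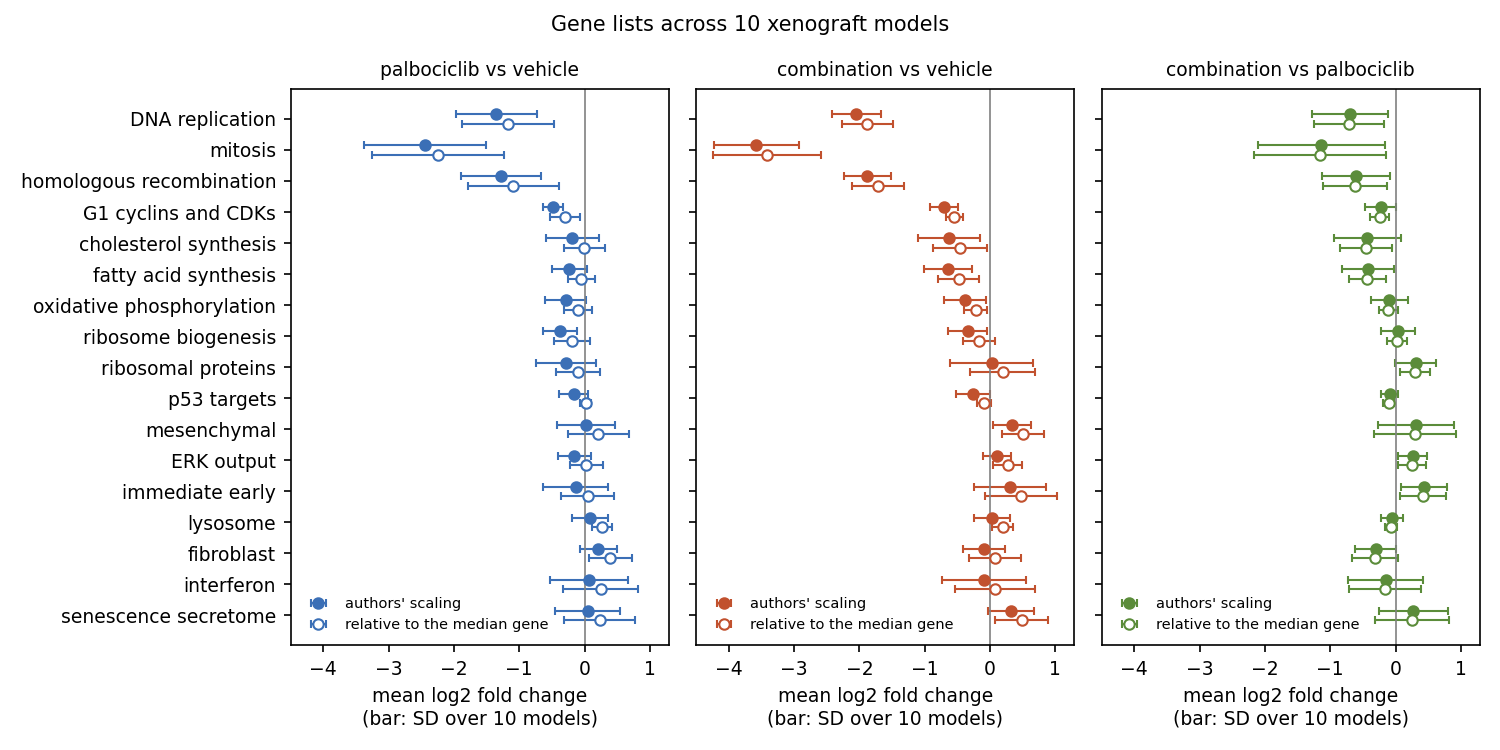
Mean log2 fold change (horizontal axes) of 17 gene lists over 10 models in the 3 contrasts, with the authors' scaling (filled circles) and relative to the median gene of each model (open circles); bars are the SD over models. The mitosis and DNA replication means lie below 0 in every panel, the cholesterol and fatty acid synthesis lists lie at -0.63 and -0.65 with the combination in the authors' scaling, and the open circles lie to the right of the filled ones against vehicle.

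The third comparison set the combination against palbociclib alone, which shows what was added with TAK228. Division genes were lower again: MKI67 was at -2.14 ± 0.43 (9 of 10 models), RRM2 at -2.04 ± 0.34 and MYBL2 at -1.85 ± 0.35 (SE, 10 of 10 models), with limma adjusted p of 0.0487, 0.0421 and 0.0421. FAM111B (-1.64), CLSPN (-1.42), DTL (-1.35), NCAPH (-1.22), SHCBP1 (-1.22), FAM83D (-1.21), POLQ (-1.19), E2F1 (-1.18), EXO1 (-1.16), BRIP1 (-1.06) and CENPA (-1.05) fell too. The mitosis list changed by -1.14 ± 0.97 (SD, 9 of 10 models) with an exact sign-flip adjusted p of 0.0219. The DNA replication list changed by -0.70 ± 0.58 and the homologous recombination list by -0.61 ± 0.53, both in 8 of 10 models with an adjusted p of 0.0432. Members past the threshold were 7 of 48, 9 of 47 and 3 of 19, against 48, 34 and 16 adjusted over the list alone. The mitosis list ranged from -2.81 in model G, -2.30 in H and -2.04 in F to -0.17 in D and 0.09 in J. Without models E and F, in which title tags differ between treatments, none of the 3 lists passed. The mitosis list was at -1.04 (adjusted p = 0.0571), the DNA replication list at -0.63 and the homologous recombination list at -0.57 (adjusted p = 0.103 for both). With fewer models the smallest p of the test is larger, and the means moved little. The lost calls therefore do not show that models E and F carried the falls. Without combination 1 or palbociclib 3 of model D, the mitosis list was at -1.09 or -1.10 (adjusted p = 0.0547 or 0.0518) and the DNA replication list at -0.64 or -0.66 (adjusted p = 0.0853 or 0.0703). Without palbociclib 1 of model B the DNA replication list was at -0.65 (adjusted p = 0.0522). Among libraries sharing a tag, the mitosis list was at -1.74 in model F (3 against 2 libraries) and at -2.20 in model E (3 against 1). In model C the libraries without the suffix LT lay close together. Against vehicle they were at -2.98 with palbociclib and -3.07 with the combination (1 library each). Those with the suffix were at -0.99 and -2.50 (2 each).

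Higher with the combination than with palbociclib were AKAP12 (1.71 ± 0.29, 3.28-fold), PDGFB (0.87), MAFF (0.85), TGFBI (0.82), TNFAIP3 (0.80), PLAUR (0.77), PEAR1 (0.73), CLCF1 (0.73), TPT1-AS1 (0.72) and AMY2B (0.72), each in at least 9 of 10 models with a limma adjusted p between 0.0421 and 0.0448. AMY2B shares reads with near-identical amylase genes, and TPT1-AS1 is an antisense gene whose reads cannot be separated from its partner without strand, so both are uncertain. IRS2, an insulin receptor substrate, was 0.75 ± 0.16 higher in 10 of 10 models and missed the threshold (adjusted p = 0.0525), but passed without the 3 libraries that stand apart (0.79, adjusted p = 0.0284). CCND2 was at -1.06 ± 0.24, lower in 10 of 10 models (adjusted p = 0.0536), and LUM at -1.35 ± 0.33, also in 10 of 10 (adjusted p = 0.0631). CCND1 (0.08), CDK4 (-0.08), CDK6 (0.01), CCNE1 (-0.32), CCNE2 (-0.51), CDK2 (-0.28), RB1 (-0.28), CDKN1A (0.24), CDKN1B (0.24) and MYC (0.19) did not pass, with adjusted p from 0.144 to 0.987.

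Lists that rose in this comparison were those of immediate early genes, which also answer to handling of the tissue (0.44 ± 0.35, SD, 9 of 10 models, exact sign-flip adjusted p = 0.0219), ERK output (0.26 ± 0.22, 10 of 10 models, adjusted p = 0.0137) and ribosomal proteins (0.31 ± 0.32, 9 of 10 models, adjusted p = 0.0469). No member of the 3 lists passed over all genes. Adjusted over the list alone, 8 of 17, 5 of 17 and 31 of 38 were higher. Against vehicle the 3 lists were at -0.13, -0.155 and -0.28 with palbociclib and at 0.31, 0.105 and 0.02 with the combination. In the authors' scaling none of these passed (exact sign-flip adjusted p from 0.179 to 0.92). In that scaling the rises over palbociclib are therefore not shown to be rises over vehicle. Relative to the median gene, the ERK output list did pass for the combination against vehicle, as given above. Against palbociclib, immediate early genes missed the threshold without models E and F, where fewer models are tested (0.38, adjusted p = 0.0571). So did ribosomal proteins (0.30, adjusted p = 0.103). The fatty acid and cholesterol synthesis lists stood at -0.42 ± 0.40 and -0.44 ± 0.51 (adjusted p = 0.0522 and 0.0879) and passed relative to the median gene, at -0.43 ± 0.28 and -0.45 ± 0.40 (adjusted p = 0.0149 and 0.0304). The G1 list stood at -0.23 ± 0.23 (adjusted p = 0.0571) and, relative to the median gene, at -0.25 ± 0.14 (adjusted p = 0.0109). In the same way p53 targets (-0.11), mitochondrially encoded genes (0.13), FOXO targets (0.16), lysosome (-0.07) and antigen processing genes (-0.13) passed only relative to the median gene, with adjusted p from 0.0109 to 0.0447. The fibroblast list stood at -0.30 ± 0.31 (adjusted p = 0.0905).

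In total 71 genes changed between the combination and palbociclib, 26 higher and 45 lower, with the median of all genes at 0.02, and 2323 genes had an unadjusted p under 0.05. This count sits at the edge of the threshold: it was 30 (5 higher, 25 lower) with centring and 107 with TMM factors, 0 under 5 other settings and 1246 in 1 limma fit that takes mice as replicates. Every named gene of this contrast lost its call under at least 1 setting, while the mitosis list lost its call only without models E and F or without either of 2 libraries of model D. The DNA replication list also lost its call with any model but A or D left out, where fewer models raise the smallest p. Models A and D were those in which this list was higher (0.06 and 0.27). Within single models limma called a median of 4.5 genes, from 0 in models B, H and J to 2263 in model E, where 2 palbociclib libraries stand apart; at an unadjusted p under 0.05, limma counted 910, 1085 and 752 genes in B, H and J, where chance alone gives about 686, 678 and 670. The median ran from 2 to 25 with 1 mouse left out.

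**Figure D3:**
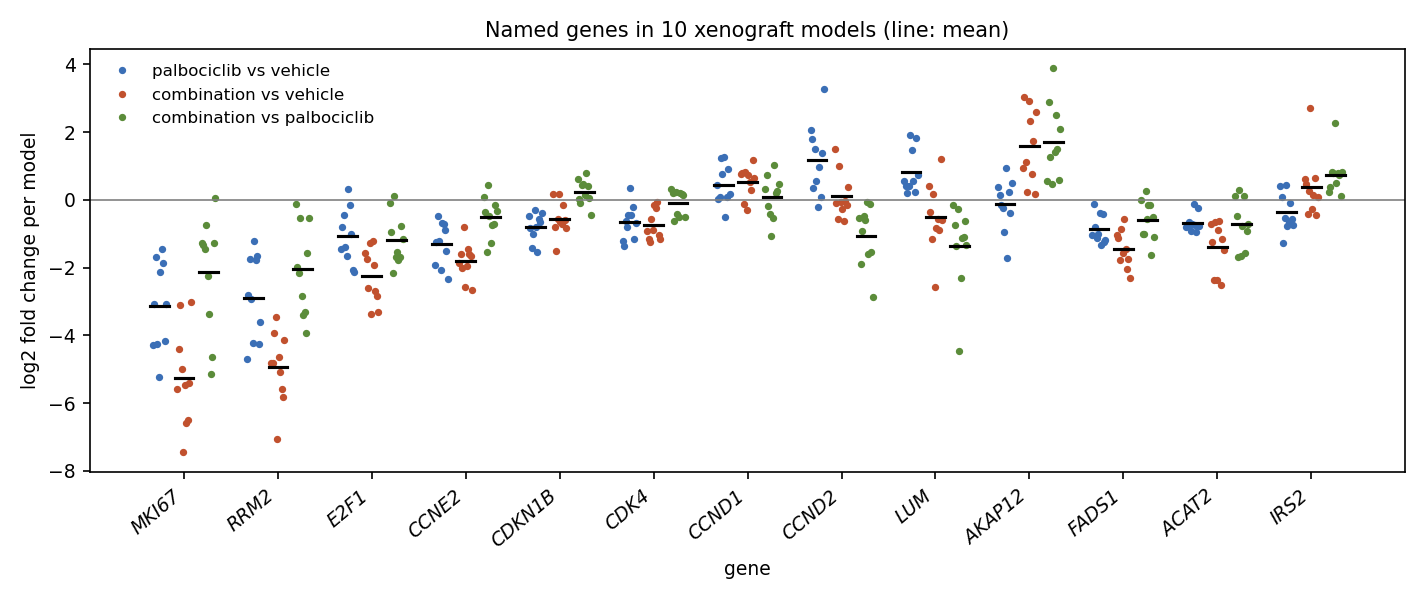
Log2 fold change (vertical axis) of 13 genes (horizontal axis) in each of 10 models, 1 point per model and a black line for the mean, for the 3 contrasts in colours. MKI67 and RRM2 lie below 0 in every model against vehicle, CCND2 and LUM have means of 1.17 and 0.83 with palbociclib and of -1.06 and -1.35 in the combination against palbociclib (the last 2 did not pass), and AKAP12 lies above 0 in every model with the combination.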

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

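All explanations weighed in this part were tested after the results were seen, except the share of reads in the most abundant genes and the other splits of the samples.

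The response of 5 gene lists differed between models beyond the spread between mice, by an interaction permutation test over 60 libraries per contrast. For genes of cholesterol synthesis F was 2.933 for the combination against vehicle and 3.009 against palbociclib (adjusted p = 0.046 for both). For fatty acid synthesis F was 3.384 for the combination against vehicle (adjusted p = 0.0257). For the mesenchymal list F was 2.905 for palbociclib against vehicle (adjusted p = 0.046) and 4.371 for the combination against palbociclib (adjusted p = 0.00682). For immediate early genes F was 4.436 for palbociclib and 4.022 for the combination, each against vehicle, and for ribosomal proteins F was 4.327 for the combination against vehicle (adjusted p = 0.00682 for the last 3). Of these 8 differences none held without models E and F, 3 held without the libraries of model C with the suffix LT, 4 held without the 3 libraries that stand apart, and 5 held with the 2 doubtful combination libraries of model I averaged.

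A single model lay far from the other 9 in 8 of 174 sets of 10 model values, where chance gives about 8.7. Model E stood out in 4 of them. With the combination against vehicle, IRS2 was at 2.71 in model E (next highest model 0.65) and MMP9 at 4.43 (next 2.34). With the combination against palbociclib, IRS2 was at 2.28 in model E (next 0.83) and the mesenchymal list at 1.76 (next 0.79). In model F, palbociclib left CDK2 at 0.0573 (next highest -0.46) and the fatty acid synthesis list at 0.386 (next -0.05). KIF20A, a kinesin of cell division, was at -2.25 with the combination in model J (next -3.69), and the amylase gene AMY2B was at 1.68 in model D against palbociclib (next 0.91).

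Palbociclib libraries 1 and 2 of model E stood apart from the other 7 libraries of that model. The depths argue against low depth as the source, since 5 other libraries of the model had fewer reads than the better covered of the pair. The role of palbociclib alone cannot be decided, because the pair was picked for standing apart. The third palbociclib library had a median correlation of 0.925 across genes with the 6 vehicle and combination libraries. That library carries another tag in its title, and its median correlation with the vehicle libraries exceeded that of the pair by at least 0.0957, but it does not share the tag of the vehicle libraries either and the pair was picked for standing apart, so this decides nothing about the line or passage behind the tag, which stays open. In model F, however, palbociclib libraries with different tags correlated at 0.984 and 0.987, against 0.985 for a pair with the same tag, and no biological difference between these tumours was tested.

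Far more genes were lower than higher with palbociclib across models in the authors' scaling, while within models E and F more calls were higher (1091 and 1472) than lower (804 and 1140). The tables argue against a few genes taking most of the reads, since the share of the 10 most abundant genes was higher than with vehicle in 5 of 10 models. With TMM factors the share of lower calls was 71.9%, against 98% in the authors' scaling, but TMM sets the typical gene near 0 whatever moved it, so this does not decide the source. With libraries rescaled to the same total, the median gene was at -0.0098, against -0.1762 in the authors' scaling. Then 726 genes changed, 193 higher and 533 lower. The shift of the median gene thus goes with the column totals of the authors' scaling, while lower calls still outnumbered higher ones. Equal totals take out any shift shared by all genes, whatever moved it, so this does not decide the source either. Less mRNA per tumour cell was not tested, since reads without an added RNA standard hold no measure of it. Relative to the median gene all 48 mitosis genes were still lower.

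The number of genes called per model with palbociclib ran from 0 to 3031. Depth gave a Spearman rho of 0.134 over 10 models (permutation p = 0.711, adjusted p = 0.711) and r = 0.0801 (p = 0.815, adjusted p = 0.815). Without the 2 farthest models r was 0.13. No relation with depth was seen, but 10 models cannot exclude one. The spread between mice of a group gave rho = -0.717 (permutation p = 0.024, adjusted p = 0.072) and r = -0.791 (p = 0.00451, adjusted p = 0.0135), but r was -0.465 without the 2 models farthest from the median. The size of the mitosis list fall gave rho = 0.438 (p = 0.205, adjusted p = 0.308) and r = 0.58 (p = 0.0824, adjusted p = 0.124), with r = 0.402 without the 2 farthest models. Spread and size of response cannot be told apart as sources with 10 models, depth is not excluded, and 3 relations were computed in this family.

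Other splits of the samples were counted in 100 draws per result, the real one included. Swapping palbociclib and vehicle within models gave at most 0 genes besides the real 2769 (1 of 100 draws as large). Swapping the combination and vehicle gave at most 575 besides 2517 (1 of 100). No swapped draw reached the real count in either contrast. For the combination against palbociclib 2 of 100 draws reached the real 71, and the highest other draw gave 121 genes. This share is under 0.05, but a split with more genes than the real one shows how unsteady this count is, so chance is not excluded for it. For the median of genes per model, 1 of 100 draws was as large in each contrast: the real medians were 803, 955.5 and 4.5, and the highest others 121, 0.5 and 1. In single models the real split called the most genes of the 10 splits in 7, 10 and 5 of 10 models, and another split reached 2246, 674 and 263 genes in 1 model, which points to structure among the mice besides the treatments.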

How the results depend on the processing

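The settings with voom, the deposited log2 values as they stand, without the LT libraries and without the 3 libraries that stand apart were chosen after the data were seen. The planned edgeR and DESeq2 alternatives were left out by choice, since the deposited unit is log2 and not counts, although the recovered reads would have allowed them; voom on those reads was run in their place. No paired analysis was possible because the labels give no number that pairs mice across treatments, and the model is already the block.

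For the mitosis and DNA replication lists, 82 of 84 values under other settings kept direction and side of the threshold. The other two were those of the combination against palbociclib without models E and F, at -1.04 and -0.633, where fewer models are tested. Against vehicle both lists kept their calls throughout, with any model or mouse left out too. Of 1014 values of the other lists, 930 kept their side, 15 lost and 68 gained a call, and 1 reversed: antigen processing with palbociclib was at 0.1177 when centred on the median gene, because centring removes the negative shift. Of the named genes called, 26 of 35, 48 of 53 and 0 of 26 kept their calls in every setting, for palbociclib, the combination and their difference.

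The number of genes changed with palbociclib (2769) was 726 with libraries at the same total, 841 with TMM factors, 974 centred and 752 with voom, 4338 without models E and F, and 5184 in 1 fit over the 90 libraries, which takes mice as replicates. For the combination (2517), that fit gave 5962. For the combination against palbociclib (71), the count was 0 with a pseudocount of 5, no filter, medians of mice, without models E and F or without the LT libraries. It was 30 centred, 107 with TMM factors, 122 with 2 combination libraries of model I averaged, 132 with a pseudocount of 0.1, 157 with voom, 158 with the deposited log2 values, 388 without the 3 libraries that stand apart and 1246 in the fit over the 90 libraries. Where construction does not show it, the cause was not tested.

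The median of genes per model was 294 with palbociclib without a filter, against 803 with it, and from 557 to 823 under the other settings. With the combination (955.5) it was 484.5 with no filter, 622 with TMM factors, 399 without models E and F and 544 with voom. Against palbociclib (4.5) it was 2.5 with a pseudocount of 5 or without trend, 0 with no filter, 2 without models E and F, 43.5 with only the 6 libraries compared and 0.5 with voom; the cause was not tested.

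With 1 model or 1 mouse left out, the counts ran from 1780 (without model D; 1811 without J) to 3398 with palbociclib, from 1576 (without model J) to 2892 with the combination and from 0 to 276 between them. In this last comparison the mitosis list ran from -1.276 to -0.9545 and the DNA replication list from -0.8038 to -0.6101. The latter lost its call with any model left out but A or D, the only models in which it rose. The median of genes per model ran from 502 (without combination 2 of model J; 542.5 without combination 1) to 2118 (without vehicle 3 of J) with the combination, and from 2 to 25 against palbociclib. In simulated data at the depths of these libraries, 33.3% of 2-fold changes, drawn from the better expressed genes, were called inside a model. What other depths would give was not tested.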

Other observations

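The tests in this part were chosen after the result was seen, except the matching by level.

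Mitosis genes fell further than DNA replication genes with palbociclib. The difference of the 2 list means was -1.08 ± 0.46 (SD, n = 10 models, exact sign-flip p = 0.00195, the smallest the test can give), below 0 in 10 of 10 models. With the combination it was -1.53 ± 0.73 (9 of 10 models, exact sign-flip p = 0.0039), and between the combination and palbociclib -0.44 ± 0.66 (8 of 10 models, p = 0.0645, exact sign-flip). Among 38 pairs of members matched by level within 0.5 log2 the difference with palbociclib was -1.07 ± 0.46. The levels matched were means over all treatments, which the falls themselves lower. The matching therefore does not decide whether the level of the genes plays a part. A deeper loss of mitotic than of S phase transcripts remains a hypothesis, found and tested on the same data.

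Interferon-stimulated genes may rise when CDK4 and CDK6 are inhibited. With TMM factors the interferon list stood at 0.25 ± 0.60 (SD, n = 10 models) with palbociclib, higher in 7 of 10 models, with an exact sign-flip p of 0.26. This leaves the question open at 10 models.

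The column totals after undoing the logarithm differed from vehicle by -11.7% ± 13.2 (SD) on average with palbociclib, and were lower in 8 of 10 models (exact sign-flip p = 0.0273). With the combination the difference was -7.75% ± 14.5, also in 8 of 10 models (exact sign-flip p = 0.111). In model B, palbociclib library 3 had a median correlation across genes of 0.815 with the 8 other libraries, and the lowest median of those 8 among themselves was 0.917.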
